A study of Bifidobacterium longum with 4 samples.

How the data were processed

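Total RNA of Bifidobacterium longum NCC2705, a Gram-positive gut bacterium used as a probiotic strain, was compared on 2-colour DNA microarrays between times of one continuous culture in an MRS medium with cysteine. RNA taken at 134 h was hybridised against RNA taken at 31 h on 2 arrays, and RNA taken at 211 h against RNA taken at 31 h on 2 further arrays. Per the labels, the 2 arrays of each comparison were technical replicates with exchanged dyes: array 1 carried the later time in Cy5 and array 2 carried it in Cy3. Per the labels, cDNA was labelled with a dendrimer kit. One label field of the second channel gives 0 h where its treatment field and the series' design text give 31 h, and 31 h was used here.

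The deposited scanner values are intensities: the mean and the median brightness of each spot and of its local background, in each dye, with no background correction or normalization. They were made with ImaGene 5.6.0 and a fixed circle for each spot, per the file headers. The deposited value table holds log2 ratios, and limma is the only tool named, per the submitters' processing notes, with no version. Scale and direction of that table were found by setting each column against the scanner ratios of the same array: among spots brighter than 9 on the log2 scale the correlation across spots was 0.984 to 0.996 and the slope 0.964 to 0.991, so its values are log2 of the later time over 31 h on all 4 arrays. Its column medians were -0.075 and 0.038 for the 134 h arrays and 0.011 and 0.044 for the 211 h arrays; how the columns were centred is not given in the sources used here. That table holds values for 5751 to 9381 of the 10807 spots per array. It served only as an alternative, without the filter on dim probes.

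Each array had 10807 spots, of which 10095 were probes for 1744 features: 1724 loci with a BL identifier, 19 reading frames of insertion sequences and the transfer-messenger RNA gene ssrA. A feature had 4 to 6 probes (4 probes for 123 features, 5 for 123 and 6 for 1498). The files pair the BL identifiers with no gene name or product. The reference table given for the species lists 2036 genes of another strain, and 0 of the BL identifiers matched it, so loci are given by identifier only and at most 2 higher and 2 lower loci are named for each comparison. Of the 21 gene lists fixed before the data were examined, 20 had fewer than 3 members with a name and were void; the list of mobile elements had 19.

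Calculations were done in R 4.3.3 with limma 3.58.1. Mean spot intensities were corrected with the median local background by normexp with an offset of 50, and each array was normalized by a global loess curve with a span of 0.3, with control spots and spots marked by the image software at weight 0. The marked spots, 4 and 4 on the 134 h arrays and 725 and 9 on the 211 h arrays, were left out. The log2 ratio of each probe was turned to the later time over 31 h, the median was taken over a feature's probes, and the 2 dye-swapped arrays were averaged, so that a constant dye effect cancels. The offset pulls ratios of dim spots towards 0. A probe was above background where its median brightness exceeded its local background by more than 2 background SDs, and a feature was measured in a comparison where at least 1 probe was above background in at least 1 channel on both arrays. A level not above background on both arrays gives only a bound on the fold, taken from the bright channel against the higher of the dim channel's own value and the lowest value above background; channels were compared after loess and Aquantile scaling.

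Because both arrays of a comparison hold the same pair of RNA extracts, each comparison is 1 replicate. No p-value for culture time was computed, and the number of arrays limits the precision. A feature was counted where its mean log2 ratio was at least 1 in size (2-fold) and both arrays had its sign. The difference between 211 h and 134 h was taken through the 31 h RNA and counted where it was at least 1 in size and both 211 h arrays lay on the same side of both 134 h arrays. The measurement error is the deviation of an array from its pair's mean, which holds dye bias and array noise but not the spread between cultures, samplings or RNA extractions. The SD given with a locus is that of its 2 arrays.

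The calls were tested on simulated data with the measured intensities and probe noise, with 50 genes changed at each size. Noise was drawn separately for each probe, without error shared by a gene's probes or spread between extracts. For 134 h against 31 h, with 1543 genes, the rule found 10.0% of the genes set at 2-fold, 72.0% at 3-fold and 84.0% at 4-fold, and 0 of 1343 unchanged genes. For 211 h against 31 h, with 1500 genes, it found 22.0%, 84.0% and 92.0%, and 0 of 1300 unchanged genes. With such noise both counts of 0 were nearly fixed in advance, so they are no test of false calls. A true log2 ratio of 1 was recovered as 0.76 and 0.80, so in this respect the counts of 2-fold genes are low estimates. A true log2 ratio of 0.58 (1.5-fold) was recovered as 0.42 and 0.43, so genes changed 1.5-fold would often lie within 1.5-fold here.

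The rule for naming genes took, per comparison with 31 h, the 12 highest and 12 lowest features with a gene name, the next largest filling the places as values only; the largest member of each list; the 5 highest and 5 lowest loci without a name as a group; and runs of at least 3 consecutive locus numbers past 2-fold in one direction. For 211 h against 134 h it took the 5 highest and 5 lowest. With 20 named features in all, the first part yields insertion sequences and ssrA only. Insertion sequences occur in near-identical copies, so their ratios are sums over copies and uncertain for any single copy.

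The slide and the day of image analysis, read from the file headers, put both 134 h arrays on slide 1 and day 1, the first 211 h array on slide 2 and day 2, and the second on slide 3 and day 3. No slide held both comparisons, so slide and comparison cannot be told apart.

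Alternatives were no background correction, plain subtraction, median centring, loess with Aquantile scaling, no filter and a stricter filter on dim probes, the mean over probes, a 1.5-fold threshold, 2-fold on both arrays, each array alone, limma over arrays with and without the replicate number as a block, and the submitters' table. 3 more were chosen after seeing the data: the median over only the probes above background, median spot brightness with plain subtraction and an offset, and subtraction of the median of each stretch of 40 locus numbers. The simulation of shared genes between the 2 lists was also added after the overlaps were seen.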

Results

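Gene expression of Bifidobacterium longum NCC2705 in continuous culture was measured at 31 h, 134 h and 211 h, in a series whose title names the physiological stability of the strain in such a culture. A total of 4 arrays was read: 2 dye-swapped arrays of 134 h against 31 h and 2 of 211 h against 31 h, all technical replicates of 1 RNA pair per comparison. Of the probes, 43.8% and 83.1% were above background in the 134 h channel and 61.4% and 55.8% in the 31 h channel of the same arrays. On the 211 h arrays the shares were 69.4% and 61.2% for 211 h and 86.6% and 47.1% for 31 h. Negative-control spots were above background in 0% to 1.27% of cases in Cy5 and in 1.27% to 20.3% in Cy3, the highest share being on the first 211 h array.

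At 134 h, 29 genes were at least 2-fold higher and 19 at least 2-fold lower than at 31 h, which together were 3.11% of the 1543 measured genes. The highest were the consecutive loci BL0981, 24.6-fold above 31 h (log2 ratio 4.62 ± 0.45, SD of 2 arrays), and BL0980, 16.9-fold above (4.08 ± 0.25). The lowest were BL1196, 6.75-fold below 31 h (-2.75 ± 0.39), and BL1197, 4.22-fold below (-2.08 ± 0.40). The 5 highest loci lay between 5.13-fold and 24.6-fold above 31 h, and the 5 lowest between 2.77-fold and 6.75-fold below. Runs of consecutive loci passed together: 4 loci were 3.06-fold to 4.53-fold higher, another 3 were 5.13-fold to 10.4-fold higher, and 3 loci that include BL1196 and BL1197 were 2.69-fold to 6.75-fold lower. In all, 6 genes were at least 4-fold higher and 2 at least 4-fold lower, while 84.8% of the measured genes lay within 1.5-fold of their 31 h level. Simulated 1.5-fold genes were recovered at a log2 ratio of 0.42, so this share may be too high.

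The spread of the 134 h log2 ratios across genes (SD 0.475) exceeded that of the arrays' deviations from their pair mean (SD 0.177), and 0 genes had a deviation of 1 or more, the size that counts as 2-fold. The 2 arrays correlated across genes with r = 0.760 (Spearman 0.645), genes not being independent replicates. All probes of a gene had the gene's sign in 46 of the 48 genes. The second array alone gave 76 genes, 46 higher and 30 lower, against 44 for the first alone. Median centring in place of loess gave 28 higher and 29 lower genes.

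At 211 h, 64 genes were at least 2-fold higher and 41 at least 2-fold lower than at 31 h, 7.0% of the 1500 measured genes. The same loci had the most extreme ratios: BL0981 was 42.2-fold above 31 h (log2 ratio 5.40 ± 0.31) and BL0980 23.5-fold above (4.56 ± 0.11), while BL1196 was 11.5-fold below (-3.53 ± 0.10) and BL1197 4.62-fold below (-2.21 ± 0.68). The 5 highest loci were 15.7-fold to 42.2-fold above 31 h and the 5 lowest 4.38-fold to 11.5-fold below. At least 4-fold changes were found for 14 higher and 9 lower genes. Within 1.5-fold of 31 h lay 80.9% of the genes, a share that may be too high for the same reason as at 134 h.

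Runs of consecutive loci at 211 h comprised 6 runs of higher genes, with 20 genes in all, and 2 runs of lower genes, with 10 genes. The 3 loci that were 5.13-fold to 10.4-fold higher at 134 h were 15.7-fold to 19.4-fold higher at 211 h. The run of 4 higher loci at 134 h was part of a run of 5 at 211 h, 2.15-fold to 6.0-fold higher. The run that includes BL1196 and BL1197 comprised 6 loci, 2.12-fold to 11.5-fold lower; 1 of them was not well above background at 211 h on either array and is bounded as at least 2.1-fold lower. A run of 4 other loci was 3.65-fold to 4.54-fold lower at 211 h, and its log2 ratios at 134 h lay between -0.28 and 0.14.

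The arrays' deviations at 211 h had an SD of 0.174 against an SD of 0.609 for the log2 ratios, and 0 genes deviated by 1 or more. The 2 arrays correlated across genes with r = 0.849 (Spearman 0.728). All probes of a gene had its sign in 100 of the 105 genes. The submitters' value table gave 181 genes, 124 higher and 57 lower, with the same 2-fold rule but without the filter on dim probes. Without that filter the main processing still gave 105 genes. The submitters' table holds only 7544 and 5751 values on the 211 h arrays, so its medians rest on fewer probes. Where a probe had to be above background in both channels on both arrays, 92 of the 105 genes remained, 54 higher and 38 lower.

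**Figure D1:**
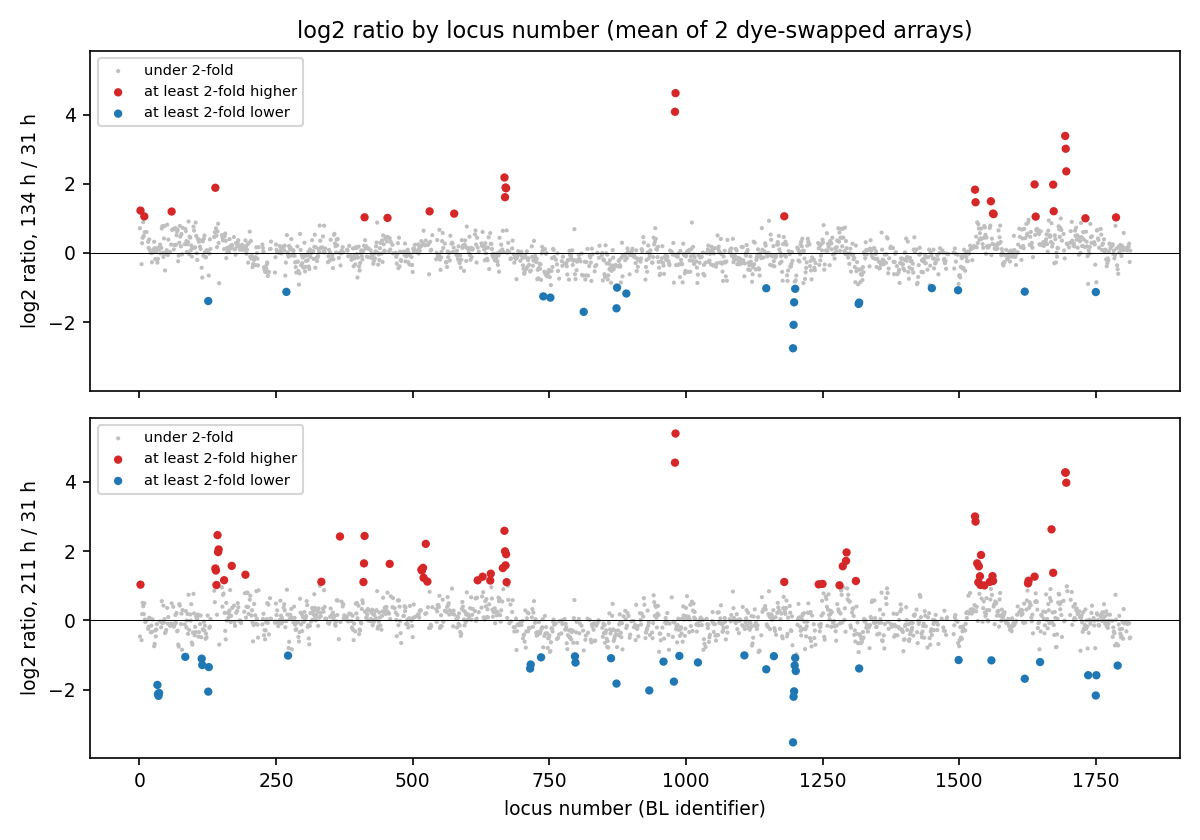
Log2 ratio of each measured locus over 31 h (vertical axes, mean of 2 dye-swapped arrays) against the number in its BL identifier, at 134 h (top) and 211 h (bottom). Red points are loci at least 2-fold higher, blue points loci at least 2-fold lower and grey points all others; the extreme points are BL0981 at 4.62 and 5.40 and BL1196 at -2.75 and -3.53.

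Between 134 h and 211 h, 27 of 1452 genes were at least 2-fold higher at 211 h and 16 at least 2-fold lower. BL0367 was 5.33-fold higher at 211 h than at 134 h, with log2 ratios over 31 h of 0.01 ± 0.28 at 134 h and 2.42 ± 0.38 at 211 h. Over only its probes above background BL0367 had 1.54 at 134 h and 2.40 at 211 h, less than 2-fold apart. BL0524 was 3.60-fold higher, with 0.36 ± 0.06 at 134 h and 2.21 ± 0.29 at 211 h. BL0035 was 5.02-fold lower at 211 h, with 0.14 ± 0.31 at 134 h and -2.18 ± 0.13 at 211 h, and BL0036 was 4.60-fold lower, with 0.10 ± 0.28 and -2.10 ± 0.15. The 5 highest loci differed by 3.41-fold to 5.33-fold and the 5 lowest by 3.37-fold to 5.02-fold. The run of 4 lower loci that holds BL0035 and BL0036 passed in this comparison too, as did 2 runs of 3 higher loci each. The difference passed through the 31 h RNA on different slides; its SD across genes was 0.432, that of the combined array deviations 0.232, and 0 genes reached 1 in the latter. The count depended on the arrays used: the second array of each pair alone gave 65 genes (31 higher, 34 lower) and the first alone 71 (44 higher, 27 lower). Plain background subtraction gave 65 genes, the median over only the probes above background 72, the values of the submitters 89, and 2-fold separation of all arrays 24. Median centring gave 38 higher and 11 lower genes.

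Of the 29 genes higher at 134 h, 18 were also at least 2-fold higher at 211 h, and of the 19 lower genes 10 were also lower. Of the 48 genes, 47 had the same sign at 211 h. Independent lists would share 1.26 and 0.537 genes, but both lists are ratios over the same 31 h RNA. Over all 48 genes the 211 h log2 ratio was 0.839 times the 134 h ratio in the median, and 27 of them lay closer to 0 at 211 h. These 48 genes were selected by their 134 h size, which by itself favours a smaller ratio at 211 h. The median was 1.18 over the 28 genes past 2-fold at both times, which were selected by their 211 h size, and 0.49 over the other 20. Across the 1452 genes measured at both times, the log2 ratios correlated with r = 0.717 (Spearman 0.615) and 70.3% had the same sign. The counts of 48 and 105 genes are not a test that more genes differed at 211 h.

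Both comparisons contained 31 h RNA, which gives a correlation by itself. Array noise alone gave a simulated r of 0.0003. Simulated extracts that differ equally from each other, with no effect of time, gave r = 0.451 (0.381 to 0.516 in 1000 draws), a covariance of 0.141 and 64.9% of genes with the same sign, against an observed covariance of 0.215. The difference of the covariances was 0.074. Lists of the observed sizes drawn from such extracts shared 7.06 higher genes (0 to 14 in 1000 draws) and 3.83 lower genes (0 to 11) with normally distributed deviations, so the observed 18 lay above all of these draws and the observed 10 within them. With deviations drawn from the observed ratios, which have heavier tails, they shared 12.2 (5 to 21) and 8.01 (2 to 14), and both observed counts lay within that range. Of the 48 genes, 42.8 (34 to 48) had the same sign at both times with normal deviations and 39.1 (31 to 47) with the heavier tails. With 1 pair of RNA extracts per comparison the 31 h values could not be split, so part of the shared signs and overlaps may come from the 31 h RNA. After removal of array noise, the SD of log2 ratios across genes was 0.458 between 134 h and 31 h (95% bootstrap interval over genes 0.411 to 0.509), 0.594 between 211 h and 31 h (0.531 to 0.654) and 0.364 between 211 h and 134 h (0.334 to 0.394). These intervals treat genes as independent and hold no spread between extracts. They are likely too narrow, since neighbouring loci had similar ratios.

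**Figure D2:**
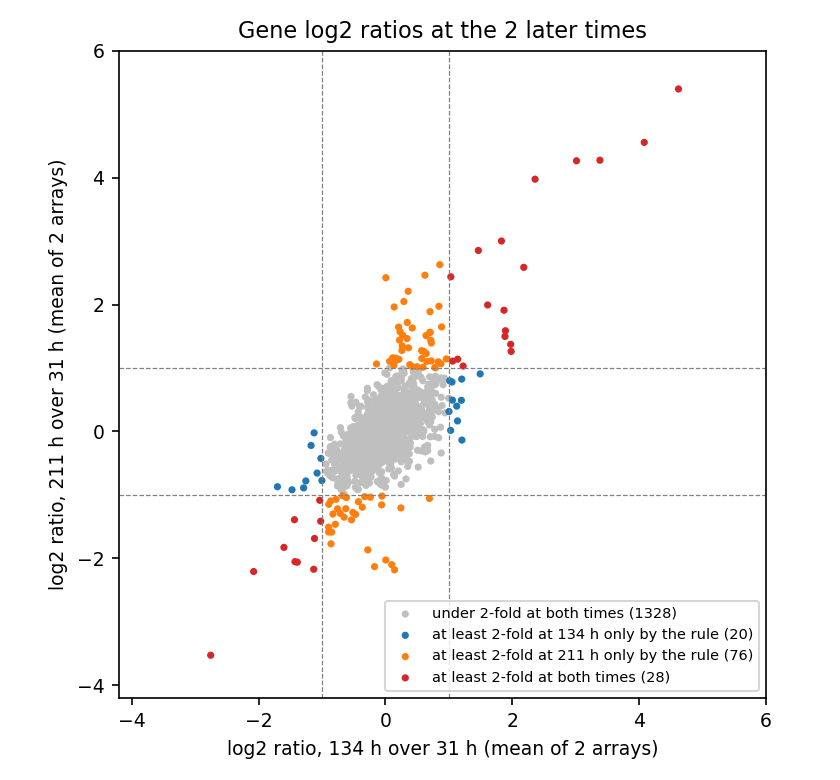
Log2 ratio over 31 h at 134 h (horizontal axis) and at 211 h (vertical axis) of the 1452 genes measured at both times, each a mean of 2 dye-swapped arrays; dashed lines mark 2-fold. Red points are the 28 genes past 2-fold at both times, blue points 20 genes past it at 134 h only, orange points 76 genes past it at 211 h only, and grey points 1328 genes under it at both.

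Mobile elements were represented by 19 reading frames of insertion sequences, short elements that carry their own transposase and move between sites of a genome. At 134 h, 17 were measured and 0 passed 2-fold. Their median log2 ratio was 0.13, at the 91.7th percentile of 10000 random gene sets of the same size and similar signal; 9 lay above 0 and 3 below 0 on both arrays. At 211 h, 15 were measured and 0 passed 2-fold, 6 were at least 1.5-fold above 31 h and 0 as far below. The count past 2-fold at 211 h depended on the processing: it was 1 without background correction, 1 with plain subtraction, 1 on the first array alone, 4 over only the probes above background and 6 in the submitters' table, all higher than at 31 h. ISBlo1a-ORFB passed in each of these, with log2 ratios of 1.09, 1.19, 1.17, 1.47 and 1.48. Their median was 0.45, above 99.96% of the random sets, and 11 lay above 0 and 1 below 0 on both arrays. The largest value was that of ISBlo1a-ORFB, 0.94 ± 0.34 at 211 h and 0.44 ± 0.15 at 134 h, followed at 211 h by ISBlo2a-ORFA2 at 0.77 ± 0.07, with 0.44 ± 0.03 at 134 h. ISBlo1a-ORFA had the largest value at 134 h, 0.56 ± 0.49, with 0.56 ± 0.23 at 211 h. The lowest at 134 h was ISBlo12-ORF2 at -0.43 ± 0.13, which was -0.12 ± 0.03 at 211 h. Counted once per element, the 10 elements had medians of 0.11 at 134 h and 0.46 at 211 h, where 9 of 10 lay above 0. The percentiles describe these RNA samples, and the frames are present in near-identical copies. At 211 h the median was 0.69 without background correction, 0.70 with plain subtraction, 0.71 over only the probes above background and 0.73 in the submitters' table; at 134 h it was 0.20 on the second array alone. The transfer-messenger RNA ssrA, which releases stalled ribosomes, had log2 ratios of 0.30 and -0.73 on the 2 arrays at 134 h. At 211 h ssrA had 0.06 and 0.08. It was very bright, with a mean log2 signal of 15.48, and whether any of its spots were saturated is not known. The small ratios of ssrA at 211 h are therefore not taken as an unchanged level.

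**Figure D3:**
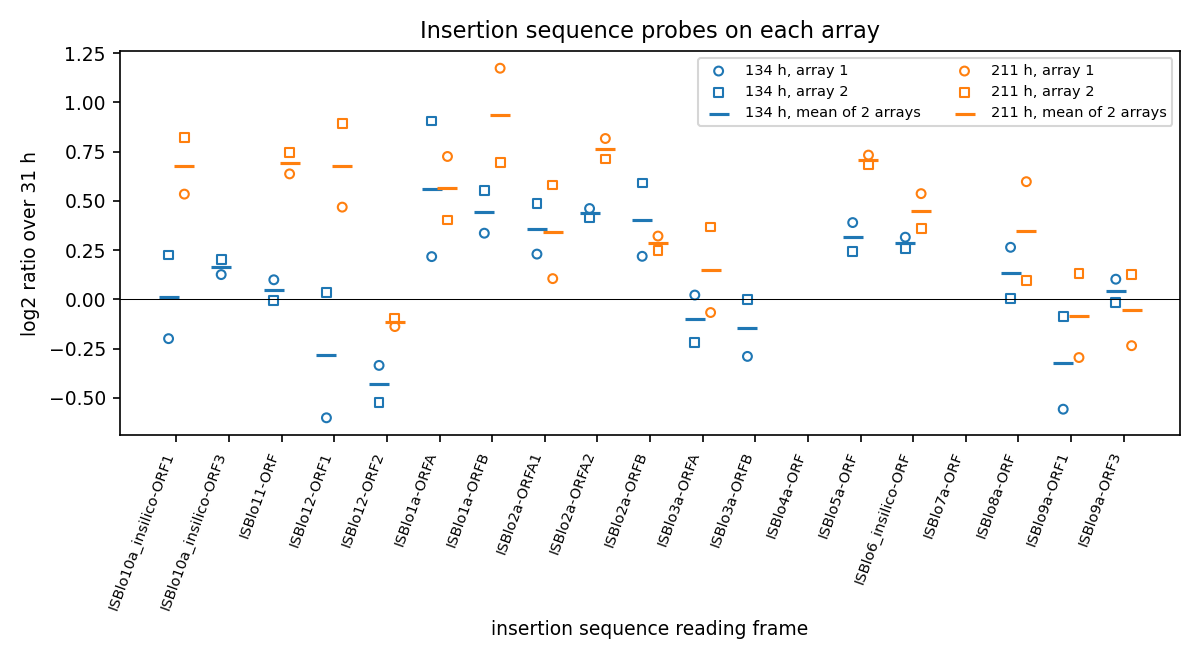
Log2 ratio over 31 h (vertical axis) of each measured insertion sequence reading frame (horizontal axis), at 134 h in blue and at 211 h in orange; circles and squares are the 2 dye-swapped arrays and bars their mean. The means reach 0.56 at 134 h and 0.94 at 211 h, and 0 of them pass 1 (2-fold) with the main processing, against 6 at 211 h in the submitters' table.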

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

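Of the tests in this part, those of array noise at 211 h, of shrinkage and of the shared 31 h RNA were chosen after the results were seen.

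More genes passed 2-fold at 211 h than at 134 h, by a ratio of 2.19, which was 1.42 on the second arrays alone (108 against 76 genes), 2.73 on the first arrays alone, 1.75 with median centring, 1.22 at a 1.5-fold threshold and 3.29 in the submitters' table (181 against 55). Over all alternatives it ran from 1.196, with limma and the replicate block, to 3.29. Larger array noise or dye bias at 211 h is argued against by the SD of the arrays' deviations, which was 0.983 times that at 134 h. Less shrinkage of ratios at 211 h stays open: the rule found 11 of 50 simulated 2-fold genes at 211 h against 5 of 50 at 134 h, while plain subtraction, which has no offset, gave a ratio of 2.65, with 1.49 on the second arrays alone, 2.77 on the first arrays alone and 1.98 among the brighter genes. Slide and day of image analysis cannot be told apart from the time, since 0 slides held both comparisons. A change of the culture between 134 h and 211 h stays open too, untested with 1 RNA extract per time.

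The correlation of the 134 h and 211 h ratios holds the shared 31 h RNA. If it came from that RNA alone, with 3 extracts that differ equally, the noise-corrected variance between 211 h and 134 h would be near the mean of the 2 variances against 31 h. Its ratio to that mean was 0.472 (95% bootstrap interval over genes 0.381 to 0.582). The interval treats genes as independent, although neighbouring loci had similar ratios, so it is likely too narrow. It holds no spread between extracts. A 31 h extract that deviates more than the other 2, for a technical or a biological reason, stays open, as does a lasting change of the culture after 31 h; neither could be tested with 1 extract at 31 h.

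Opposite directions at the 2 times were found for 4 genes, which were at least 2-fold from 31 h at 1 time while both arrays of the other time lay on the opposite side of 0. Their mean log2 ratios at 134 h and 211 h were 0.24 and -1.21, -0.14 and 1.06, 1.21 and -0.14, and 0.69 and -1.06. The smaller of each pair was under 2-fold. By this definition all 4 must also be among the 43 genes that differed at least 2-fold between 211 h and 134 h, so that adds no support. They differed by log2 ratios of -1.451, 1.203, -1.343 and -1.751. limma over arrays called all 43 against array error. The difference was not tested against the spread between cultures or extracts. The gene at -0.14 and 1.06 was very bright, with a mean log2 signal of 14.89, against a median of 9.33 for the genes past 2-fold at 211 h. Saturated gene probes numbered 2 to 15 per array, and 3 genes past 2-fold had a saturated spot. Whether the bright gene is among them is not known.

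Signal appeared in control probes that no comparison used. Probes for the control named C5-KmR had a median Cy3 brightness of at least 44531 on every array, and those for C4-Lucif 24611 and 33892 on the 134 h arrays, 8042 on the first 211 h array and 265.38 on the second, each above the 95th percentile of the negative controls.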

How the results depend on the processing

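3 alternatives were chosen after the data were examined: the median over only the probes above background, median spot brightness with plain subtraction and an offset, and subtraction of the median of each stretch of 40 locus numbers. All others were chosen before the data were examined. The planned use of median brightness was not run because normexp could not be fitted to it, and Aquantile scaling leaves the ratios within an array as they are, so it tests nothing. Limits are the single RNA extract per time, the 2 arrays per comparison, and the signal over background, since the offset shrinks the ratios of dim probes. For the named genes, 5 settings test nothing: single arrays lie within the SD of the pair by construction, and Aquantile scaling and both filters leave the values as they are. Under the others, 273 values stayed within the SD of the 2 arrays and 93 moved by more. A change of direction was looked for only in named genes past 2-fold, which were picked for their extreme ratios. That 0 of these reversed was therefore nearly fixed in advance. Features under 2-fold did change sign in some settings. ISBlo10a_insilico-ORF3 at 134 h was 0.16 in the main processing, -0.25 over only the probes above background and -0.36 in the submitters' table. The count for 134 h stayed within 1.5 times its main value of 48 except on single arrays (44 to 76), at 1.5-fold (235) and with limma over arrays. The count for 211 h (main 105) was 108 to 120 on single arrays, 286 at 1.5-fold and 181 in the submitters' table. The count between 211 h and 134 h (main 43) was 65 to 71 on single arrays, 65 with plain subtraction, 72 over only the probes above background, 190 at 1.5-fold, 24 with both arrays at least 2-fold and 89 in the submitters' table. Subtraction of stretch medians gave 37, 76 and 35 genes, of which 32, 74 and 31 were shared with the main sets. The correlation of the 2 times (main 0.717) was 0.648 to 0.676 on single arrays, 0.677 with median centring, 0.688 over only the probes above background and 0.687 in the submitters' table. The median of the insertion sequences at 134 h (main 0.13) was 0.13 to 0.20 on single arrays. At 211 h (main 0.45) it was 0.40 to 0.53 on single arrays, 0.69 without background correction, 0.70 with plain subtraction, 0.34 with no filter on dim probes, 0.57 with the mean over probes, 0.71 over only the probes above background and 0.73 in the submitters' table. The cause was not tested, except that a lower threshold admits more genes by construction.

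limma with each array as a replicate tests the RNA pair against array error, not culture time. At a Benjamini-Hochberg adjusted p under 0.05 it called 368 genes at 134 h, 486 at 211 h and 111 between them, among them all 48, 105 and 43 genes past 2-fold. With the replicate number, which is also the dye orientation, as a block over 4 arrays it called 428, 512 and 162 genes, among them 48, 104 and 43 of those past 2-fold. The arrays' deviations correlated between the comparisons with r = 0.130 across genes; with 2 numbers only, the replicate number is not taken as a pairing of samples.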

Other observations

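The tests of genomic DNA and of gene dosage in this part, and the division into stretches, were chosen after the pattern was seen.

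Genes at least 2-fold from 31 h often had a neighbour by locus number that passed in the same direction. This held for 45.8% of the numbered loci past 2-fold at 134 h, 56.9% at 211 h and 48.8% between 211 h and 134 h. The consecutive pairs past 2-fold in one direction numbered 13 at 134 h, where 10000 shuffles gave a mean of 0.66 and at most 6. At 211 h there were 36 such pairs, against a mean of 3.1 and at most 11. The log2 ratios of consecutive loci correlated with r = 0.539 at 134 h and 0.552 at 211 h across pairs.

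Medians over long stretches of locus numbers were also shifted from 0, by less than 2-fold. In stretches of 40 numbers the medians had an SD of 0.215 at 134 h and 0.208 at 211 h, against at most 0.109 and 0.117 in 1000 shuffles. Shuffles of single loci also break up the likeness of neighbours, so they cannot tell a wide shift from many short runs. Whether short runs account for the stretch medians was not tested. The 2 dye-swapped arrays correlated over the 46 stretches with r = 0.908 and 0.906. Of the 46 stretches, 41 at 134 h and 40 at 211 h had the same sign on both arrays. The ranges that follow are runs of stretches with the same sign on both arrays, picked from these data. That choice by itself moves their medians away from 0. At 134 h, numbers 0 to 199 had a median log2 ratio of 0.22 and numbers 1600 to 1839 one of 0.26. The 433 genes of numbers 680 to 1239 had a median of -0.20. At 211 h, numbers 320 to 679 stood at 0.22 and numbers 680 to 1079 at -0.22. Between 134 h and 211 h both ends of the numbering were lower at the later time: numbers 0 to 119 by a log2 ratio of -0.36 and numbers 1720 to 1839 by -0.33. With the stretch medians subtracted, consecutive loci still correlated with r = 0.411 at 134 h and 0.467 at 211 h. The shift of the stretch medians thus did not account for all of the likeness of neighbours.

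For 40 pairs of consecutive loci that passed together, the median array distance between all their probes was 0.985 times that of random probes. This argues against loci whose probes all lie close together. It would not show probes that each lie beside only 1 probe of the next locus. It covers only loci past 2-fold, so it does not bear on the shift of the stretch medians. Genomic DNA in the RNA would weigh most on dim genes. After plain background subtraction the shared shift of dimmer genes was 0.675 times that of brighter genes at 134 h (95% bootstrap interval over stretches 0.547 to 0.887). At 211 h it was 0.820 times (0.610 to 1.18). The shift was thus not larger in dim genes at 134 h. Any shrinkage of dim ratios that remains after plain subtraction would lower both values and was not measured, so the explanation stays open at both times. A candidate explanation is gene dosage along a replicating chromosome, if the numbers follow the chromosome, which the files do not state. A single cycle around the numbering took 44.3% of the variance of the stretch medians at 134 h and 10.7% at 211 h, which leaves this hypothesis open at 134 h and gives it little at 211 h. Operons that change together would give the short runs, but no operon map was used here.

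The number that ends a probe's name was read as its position in the gene, which the files do not state. Probes with high numbers were dimmer than those with low numbers of the same gene, with a difference of -0.35 to -0.46 on the log2 scale over the 4 arrays, while their log2 ratios differed by -0.016 to -0.052.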
